A study of Mus musculus with 17 samples.

How the data were processed

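Splenic B cells of male C57BL/6 mice aged 6 weeks were purified by negative selection and cultured for 2 h with interferon alpha (IFNα), a type I interferon, per the series' design text. RNA was taken in Trizol and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, which measure each transcript with a set of short probes. The 17 arrays analysed here fall into 6 groups by the dose named in the labels: 2 arrays at 0 U/ml and 3 arrays at each of 0.1, 1, 10, 100 and 1000 U/ml. The series' design text speaks of triplicates and of doses up to 10000 U/ml; another array at 0 U/ml and the 10000 U/ml dose were not analysed here. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

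The deposited values are intensity values on a linear scale, 1 per probe set and array, made by the authors with Affymetrix Power Tools and RMA (background correction, normalization between arrays and summary of probes), per the submitters' processing notes; versions are not given in the sources used here. They ran from 6.84 to 11586, and array medians lay between 100.4 and 109.5. The linear scale was settled from the values, where log2 values had been foreseen; log2 was taken before all tests and no filter on low values was applied. The interquartile range of log2 values still differed between arrays, from 2.19 to 2.63. A change shared by most genes could be lost in such a normalization. No 2 arrays held identical values. The number of arrays limits the precision.

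Of 24922 probe sets, 21425 were paired with 1 gene symbol, 1399 with several and 2098 with none in the platform's annotation. Of those with 1 symbol, 21347 were found by Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. Each of 19752 genes was represented by its probe set with the highest mean over all arrays; 921 genes had more than 1. At 1000 against 0 U/ml only Trdn had probe sets called in opposite directions. Probe sets with several symbols or none were fitted apart and are not named. The genome build of the array's design is not given in the sources used here, so no coordinates are printed, and the gene table served only for names and for which genes neighbour each other.

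The following choices were made before the data were examined, apart from those named as added. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with dose as a factor and all 17 arrays in 1 fit, so that the 2 arrays at 0 U/ml borrowed their spread from the other groups. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and a gene was called at an adjusted p under 0.05. Contrasts set each dose against 0 U/ml, each dose against the next lower one, and 1000 against 0.1 U/ml. A slope over log10 dose was fitted to the 15 arrays above 0 U/ml. For genes called up at least 2-fold at 1000 U/ml, the half-maximal dose was read from the line through the group means over log10 dose, where it first reached 0.5 of the log2 change at 1000 U/ml; a value at or below 0.1 U/ml is given as 0.1. Its error is the range over leaving out each array in turn. Contrasts against 0.5 of the 1000 U/ml response were tested at 1, 10 and 100 U/ml, adjusted over these genes. Those genes were chosen by their call at 1000 U/ml, which can overstate that response.

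The 28 fixed gene lists, with 586 of 673 members measured, were tested with camera (preset correlation of 0.01, and again with an estimated correlation), adjusted over the lists. Named genes were picked by a fixed rule: the 20 largest rises and 10 largest falls at 1000 against 0 U/ml and the 5 largest each way in the other contrasts, among called genes whose groups did not overlap; up to 4 called members of each list with the largest change, and its uncalled member with the highest mean where needed; the 5 lowest and 5 highest half-maximal doses; the 3 largest slopes each way; and Irf7, Stat1, Isg15, Ifit1, Mx1, Usp18, Cxcl10, H2-K1, Cd69, Ifnar1, Ifnar2, Cd19, Actb and Gapdh. Stat1, Isg15, H2-K1, Cd19 and Gapdh were not measured by a probe set with a single symbol and are not reported. Predicted genes were skipped, 9 in all.

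The contrasts were tested on simulated data of 19752 genes with 50 genes changed at each size. For 1000 against 0 U/ml the fit recovered 14 genes changed 1.25-fold, 43 changed 1.5-fold, 49 changed 2-fold and 50 changed 4-fold, with 5 unchanged genes called. For 1000 against 100 U/ml it recovered 15, 43, 49 and 50, with 13 unchanged genes called. The simulated noise was independent between genes and had the same spread in all groups. It held no array effect such as that of 0 U/ml replicate 2, so these counts do not show recovery in the real arrays. Alternatives covered the spread estimate, array weights, normalization, centring, low values, probe sets, the arrays in the fit, the replicate number as a block, thresholds, dose scale, response model and set test, and each array was left out in turn. Added after seeing the data were array weights by the gene by gene method, 0.1 U/ml as the baseline of the half-maximal dose, and its median over genes that moved by less than 3-fold on leaving out an array. Figures were drawn with matplotlib 3.10.9.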

Results

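Expression was measured in mouse splenic B cells after 2 h with IFNα at 0, 0.1, 1, 10, 100 or 1000 U/ml, to follow how the transcriptional response depends on dose. Replicate arrays correlated at 0.9898 to 0.9981 over 19752 genes. The lowest of these was between both 0 U/ml arrays. The first principal component held 59% of the variance and rose with dose from 0.1 U/ml (-24.3 to -21.9) to 1000 U/ml (25.7 to 27.5), with the 0 U/ml arrays at -24 and -23.9. The second held 16%, with 0 U/ml replicate 2 at 29 and the other 16 arrays between -14.3 and 14.7. That array also had the narrowest spread of log2 values, with an interquartile range of 2.19 against 2.25 to 2.63 elsewhere. The other untreated array, 0 U/ml replicate 1, correlated at 0.9965 to 0.9971 with the 0.1 U/ml arrays. Counts against 0 U/ml are therefore given with their values without each untreated array.

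**Figure D1:**
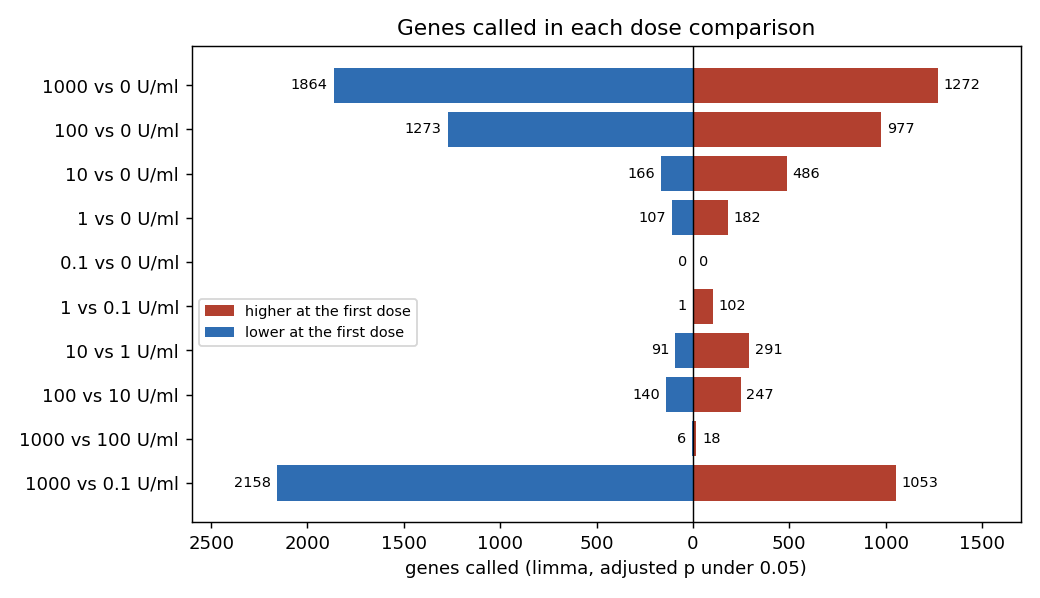
Number of genes called in each of the 10 dose comparisons (limma, adjusted p under 0.05), with genes higher at the first-named dose to the right and lower to the left. The count was 0 at 0.1 against 0 U/ml, and 24 genes (18 higher, 6 lower) separated 1000 from 100 U/ml.

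At 1000 U/ml the largest rises were in antiviral effector genes. Mx1, a GTPase gene whose protein was not measured here, rose 76.1-fold (log2 change 6.25 ± 0.17 SE, n = 3 against 2, limma adjusted p = 5e-15). Its log2 mean went from 4.34 ± 0.0015 (SD, n = 2) to 10.6 ± 0.076 (SD, n = 3). Ifit3b rose 74-fold, and Ifit3 62.7-fold and Ifit1 56.5-fold, all of a family that binds viral RNA. At 0 U/ml Ifit3b had a log2 mean of 3.51; 0.82% of genes had a lower mean there than Ifit3b and 4.6% a lower mean than Mx1, and no background level is given, so these folds are as measured and their order is not exact. Slfn5 rose 58.9-fold, Usp18, the protease that removes ISG15 from proteins and restrains receptor signalling, 55.3-fold, and the chemokine gene Cxcl10 43.7-fold. Rtp4, Mx2, Ifit2, Rsad2, Dhx58, Cmpk2, Irf7, Ifitm3, Parp12, Ifi207, Oasl2, Isg20 and Gbp7 rose between 19-fold and 39.7-fold. The largest falls were smaller. Ceacam1, an adhesion receptor, fell by 1.77 ± 0.16 on the log2 scale (SE, adjusted p = 1.6e-07), Sgms1, a sphingomyelin synthase, by 1.64 ± 0.076, and the receptor Gpr174 by 1.59 ± 0.095. Cpm, Hhex, Cd55, Kansl1, Phxr4, Gdpgp1 and Lrrc8c fell by 1.18 to 1.38 on the same scale. At 0 U/ml the SDs (n = 2) were 0.56 for Kansl1, 0.54 for Phxr4 and 0.34 for Gdpgp1. They were 0.086 to 0.28 for Cpm, Hhex, Cd55 and Lrrc8c. The size of the first 3 falls thus depends on which untreated array is used.

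In all, 3136 genes were called at 1000 against 0 U/ml, 1272 higher and 1864 lower, and 324 rose and 39 fell at least 2-fold. The median log2 change over all genes was -0.045. The count was 1992 without 0 U/ml replicate 2 and 4631 without 0 U/ml replicate 1. Falls made up 59.4% of called genes, 67.5% after quantile normalization (1346 higher, 2793 lower) and 44.3% after median centring of arrays (1379 higher, 1095 lower), so which direction held more genes depended on the scaling. With only the 1000 and 0 U/ml groups in the fit, falls were 50.3% (926 higher, 939 lower). At an adjusted p under 0.01 they were 52.5% (919 higher, 1014 lower). Among genes changed at least 1.5-fold, 641 were higher and 324 lower. The cytoskeletal gene Actb had a log2 change of 0.085 ± 0.072 (adjusted p = 0.48), and of -0.0055 without 0 U/ml replicate 2.

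Of the antiviral effector list, 52 of 56 measured genes rose and 0 fell, and 53 rose when adjusted over the list alone (camera adjusted p = 7.1e-105, 0.001 with an estimated correlation). All 12 measured interferon-inducible GTPases rose, also when adjusted over the list alone, led by Gbp7 (19-fold), Irgm1 (15.5-fold) and Gbp4 (10.4-fold). Of the list of ISGylation, ubiquitin and PARP genes, 20 of 22 rose (20 adjusted over the list alone), among them Parp12 (19.4-fold), Herc6 (14.6-fold) and Parp14 (10.4-fold). Both lists held with an estimated correlation, at an adjusted p of 0.001. Among nucleic acid sensors, 16 of 23 rose and 1 fell (17 and 1 adjusted over the list alone), with the RNA helicases Dhx58 at 22.6-fold and Ifih1 at 18.4-fold, Zbp1 at 18.3-fold and Tlr7 at 10.6-fold (adjusted p = 0.001 with an estimated correlation). Aim2 had a log2 change of -0.11 ± 0.13 (adjusted p = 0.62).

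Interferon signalling genes moved both ways: 15 of 28 rose and 4 fell (16 and 4 adjusted over the list alone; adjusted p = 0.038 with an estimated correlation). Irf7, a transcription factor of the interferon genes, rose 22.2-fold, Socs1, a feedback inhibitor of JAK kinases, 9.32-fold, and Stat2 7.41-fold. The receptor chain Ifnar1 fell by 0.56 ± 0.1 (adjusted p = 0.00049). Ifnar2 had a log2 change of -0.185 ± 0.098 (adjusted p = 0.23) at 1000 U/ml but fell by 0.35 ± 0.098 (adjusted p = 0.025) at 100 against 0 U/ml, a call lost without 0 U/ml replicate 1 or without 100 U/ml replicate 1 or 2 (log2 changes of -0.28, -0.34 and -0.25). Jak1 had a log2 change of 0.02 ± 0.082 (adjusted p = 0.93), and one of -0.13 after quantile normalization. Of 14 measured type I interferon genes, 0 were called by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.31, and 0.68 with an estimated correlation). The brightest, Ifna5, had a log2 change of -0.2 ± 0.12 (adjusted p = 0.31).

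Of 19 measured genes of MHC class I presentation, transcripts of 14 rose and of 1 fell (15 and 1 adjusted over the list alone). Camera with an estimated correlation gave an adjusted p of 0.0057. Presentation itself was not measured. H2-T24 rose 9.13-fold, Tapbp 3.92-fold, the immunoproteasome subunit Psmb9 3.14-fold and the peptide transporter Tap1 2.87-fold. B2m had a log2 change of 0.02 ± 0.062 (adjusted p = 0.9). Of 12 MHC class II genes, 3 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.23, and 0.68 with an estimated correlation; 0.0041 without 0 U/ml replicate 1 and 0.22, direction down, without 0 U/ml replicate 2). Ctss rose 1.9-fold and Ciita, the class II transactivator, fell by 0.53 ± 0.096.

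Among cytokines, chemokines and their receptors 12 of 31 rose and 3 fell (12 and 4 adjusted over the list alone; adjusted p = 0.0062 with an estimated correlation), with Cxcl10 followed by the death ligand Tnfsf10 (14.7-fold), Ccrl2 (9-fold) and Il15 (4.41-fold). Of 25 cell death and survival genes 14 rose and 0 fell, the same over the list alone (adjusted p = 0.0057 with an estimated correlation), including Xaf1 at 13.9-fold. Of 17 genes of nuclear bodies and chromatin 10 rose and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 0.01 with an estimated correlation), including Setdb2 (7.26-fold) and Pml (5.21-fold). Of 19 genes of nucleotide and tryptophan metabolism 8 rose and 0 fell (8 and 2 adjusted over the list alone; adjusted p = 0.0042 with an estimated correlation), led by Cmpk2 and Nt5c3 (9.45-fold).

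Of 39 immediate early and activation genes 12 rose and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 7e-08, but adjusted p = 0.19 with an estimated correlation). Jun rose 5.17-fold, the activation marker Cd69 3.89-fold and Myc 2.14-fold. Of 33 B cell identity and antigen receptor genes 4 rose and 10 fell (5 and 15 adjusted over the list alone). The list was not called (camera adjusted p = 0.079, and 0.63 with an estimated correlation) but was by camera on ranks (adjusted p = 0.034, down), without 0 U/ml replicate 2 (adjusted p = 1.4e-05, down) or 1000 U/ml replicate 3 (0.029); over all arrays left out in turn the p ran up to 0.65, direction up, without 0 U/ml replicate 1. Pik3ap1 rose 2.75-fold and Cxcr5 1.89-fold, while Fcer2a (CD23) fell by 0.86 ± 0.11 and the inhibitory receptor Fcgr2b by 0.65 ± 0.085. Of 30 cell cycle genes 6 rose and 2 fell, the same over the list alone (camera adjusted p = 0.0013, but adjusted p = 0.33 with an estimated correlation and 0.061 without 0 U/ml replicate 2), with the cyclin Ccnd2 at 4.11-fold.

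Of 12 NK cell markers 6 rose and 1 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0088, but adjusted p = 0.17 with an estimated correlation and 0.064 on ranks). The cytotoxic protease gene Gzmb rose 3.07-fold and Gzma 2.11-fold, and Klrd1 fell by 0.69 ± 0.093. Of 19 monocyte, macrophage and dendritic cell markers 2 rose and 4 fell, the same over the list alone (camera adjusted p = 0.51, direction up, with a median log2 change of -0.043). Mpeg1 rose 7.84-fold and Cybb 2.22-fold, while Adgre1 fell by 0.61 ± 0.1. Of 14 T cell markers 1 fell (camera adjusted p = 0.82), of 6 plasmacytoid dendritic cell markers 1 fell (0.23), of 11 neutrophil markers 0 were called (0.17), and of 9 erythroid and platelet markers 2 rose, with Car2 at 2.45-fold (0.18, direction up, with a median log2 change of -0.031). The counts were the same adjusted over the list alone. Neutrophil markers were called up by camera on ranks (adjusted p = 0.027). By fry, which does not compare a list with other genes, monocyte, macrophage and dendritic cell markers were called up (0.01) and plasmacytoid dendritic cell markers down (0.033). The erythroid and platelet list was called without 0 U/ml replicate 2 (adjusted p = 0.019).

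**Figure D2:**
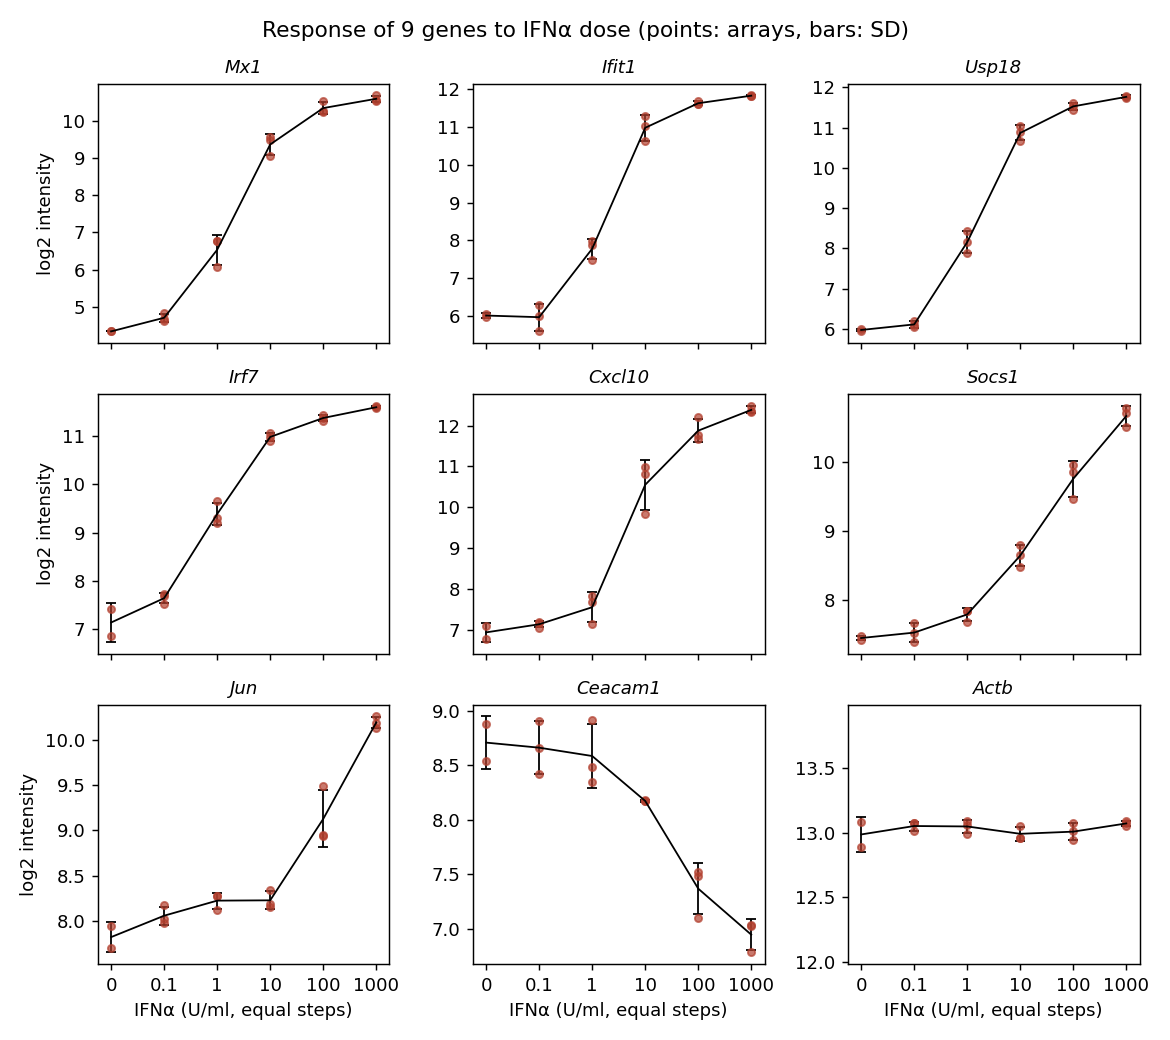
Log2 intensity (y axis, a separate range in each panel) of 9 genes against IFNα dose in U/ml (x axis, doses at equal steps); points are arrays, the line joins group means and bars are SDs (n = 2 at 0 U/ml, n = 3 elsewhere). On the log2 scale drawn here, Mx1, Ifit1, Usp18 and Irf7 had gained over 80% of their 1000 U/ml change at 10 U/ml. Jun had gained 17% on that scale. On linear values the half-maximal dose was 15.2 U/ml for Mx1, which is above 10 U/ml. It was 7.76 U/ml for Ifit1, 8.52 for Usp18, 5.04 for Irf7 and 164 for Jun.

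At 0.1 U/ml 0 genes were called against 0 U/ml by limma (2497 at an unadjusted p under 0.05; lowest adjusted p 0.345), and 2587 were called without 0 U/ml replicate 1. Irf7 had a log2 change of 0.51 ± 0.13 (adjusted p = 0.35), of 0.22 without 0 U/ml replicate 2 and of 0.79 without 0 U/ml replicate 1, where it was called, and Mx1 of 0.36 ± 0.17 (adjusted p = 0.39). The step from 0.1 to 1 U/ml raised 102 genes and lowered 1, Svs2, which fell by 0.43 ± 0.077. Log2 changes of this step use no untreated array, but its calls do, through the spread shared in the fit. The call of Svs2 was lost without 0.1 U/ml replicate 3 or without 1 U/ml replicate 1 or 3, with log2 changes of -0.38, -0.39 and -0.41. Rtp4 rose 7.52-fold, Ifit3 4.99-fold, Slfn5 4.89-fold, Usp18 4.11-fold and Trim30d 4.06-fold. Antiviral effectors gave 37 of the rises (37 of 56; adjusted p = 0.00036 with an estimated correlation). Against 0 U/ml, 289 genes were called at 1 U/ml, 182 higher and 107 lower, but 65 higher and 0 lower without 0 U/ml replicate 2 and 5250 (2464 higher, 2786 lower) without 0 U/ml replicate 1. It was 108, 128 and 118 without 1 U/ml replicates 1, 2 and 3, 175 and 190 without 10 U/ml replicates 2 and 3, 190, 440 and 758 without 100 U/ml replicates 1, 2 and 3, and 190 without 1000 U/ml replicate 1. Falls were 37% of the calls there, 54.3% after quantile normalization (142 higher, 169 lower) and 9.52% after median centring (190 higher, 20 lower).

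From 1 to 10 U/ml 291 genes rose and 91 fell. Ifit3b rose 15.5-fold, Ifit3 9.58-fold, Ifit1 9.19-fold, Ifit2 8.46-fold and Cxcl10 8-fold, and 11 of 12 GTPases rose (adjusted p = 0.0025 with an estimated correlation). Cpm fell by 0.69 ± 0.12 and Klhl14 by 0.56 ± 0.091. Leaving out 10 U/ml replicate 2 or 3, or 1 U/ml replicate 3 or 1, brought the count of 382 to 239, 230, 254 and 272. Falls were then 23, 20, 33 and 18, and rises 216, 210, 221 and 254. Without 10 U/ml replicate 1 or 1 U/ml replicate 2 falls were 40 and 45, and rises 291 and 245. Falls thus dropped whichever array of these groups was left out. Each such fit also has fewer arrays in a group, so lost precision and dependence on single arrays cannot be told apart. Falls outnumbered rises with only these groups in the fit (447 higher, 627 lower), with default array weights (922 and 1465) and with gene by gene weights (903 and 1402). Against 0 U/ml 652 genes were called at 10 U/ml (486 higher, 166 lower), 344 without 0 U/ml replicate 2, 2645 without 0 U/ml replicate 1, and 422 and 420 without 10 U/ml replicates 2 and 3. Their falls went from 25.5% to 58.7% after quantile normalization (503 higher, 714 lower). With only the 10 and 0 U/ml groups in the fit falls were 6.56% (299 higher, 21 lower). Of the 102 genes that rose from 0.1 to 1 U/ml, 96 also rose from 1 to 10 U/ml, where independent lists would share 1.5; these steps share the 1 U/ml arrays with opposite sign. From 10 to 100 U/ml 53 of them rose, against 1.3 for independent lists. That step compares no array of the lowest step, though both use the spread of the same fit.

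From 10 to 100 U/ml 247 genes rose and 140 fell, and 12 rose at least 2-fold. Gbp7 rose 2.51-fold, Cxcl10 2.5-fold, Tnfsf10 2.43-fold, and Ifit3b and Iigp1 2.36-fold each. Ceacam1 fell by 0.81 ± 0.15 and Sgms1 by 0.67 ± 0.068. The count of 387 was 112 without 10 U/ml replicate 1 and 223 without 10 U/ml replicate 2. It was 280 without 100 U/ml replicate 2 and 226 without 100 U/ml replicate 3. Falls in these fits were 25, 54, 58 and 84, and rises 87, 169, 222 and 142. Of the 387, falls were 36.2%, and they were 17.9% of calls after median centring (252 higher, 55 lower). Falls outnumbered rises with default array weights (2422 higher, 3304 lower) and with gene by gene weights (926 and 1193). At 100 against 0 U/ml 977 genes were higher and 1273 lower, 2250 in all, with 1358 called without 0 U/ml replicate 2 and 3933 without 0 U/ml replicate 1. Falls there were 56.6%, 69.7% after quantile normalization (1019 higher, 2347 lower) and 34.5% after median centring (1110 higher, 585 lower). Rises outnumbered falls there also with gene by gene weights (688 and 559), with every probe set (1561 and 1505), with only these groups in the fit (555 and 269), at least 1.5-fold (538 and 134) and at an adjusted p under 0.01 (677 and 530).

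The last step, from 100 to 1000 U/ml, called 24 genes, 18 higher and 6 lower. Jun rose 2.08-fold (log2 change 1.06 ± 0.12 SE, n = 3 against 3, limma adjusted p = 0.00064), the GTPase Iigp1 1.9-fold, Socs1 1.88-fold, the cadherin Cdh17 1.77-fold and the kinase Prkcq 1.71-fold. Sgms1 fell by 0.59 ± 0.068, Gpr174 by 0.47 ± 0.085, Rhof by 0.43 ± 0.082, Cd55 by 0.42 ± 0.066 and the chemokine receptor Cxcr4 by 0.4 ± 0.063. Of the 56 antiviral effectors 0 were called in this step, though the list as a whole was shifted up by a median of 0.13 (camera adjusted p = 8.4e-11, but adjusted p = 0.23 with an estimated correlation). Without 100 U/ml replicate 1 the calls of Iigp1, Cdh17, Gpr174, Rhof, Cd55 and Cxcr4 were lost, with log2 changes of 0.77, 0.78, -0.53, -0.43, -0.42 and -0.38; each was also lost without other arrays, whereas those of Jun, Socs1, Prkcq and Sgms1 held without any 1 array. Leaving out 100 U/ml replicate 1 or 2, or 1000 U/ml replicate 1, 2 or 3, brought the count to 4, 9, 13, 10 and 9. With only these groups in the fit limma called 0. Falls were 25% of it and 40% after median centring (6 higher, 4 lower). Falls outnumbered rises with default array weights (1531 higher, 1665 lower) and without 1000 U/ml replicate 3 (4 and 5).

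Between 1000 and 0.1 U/ml, the ends of the treated series, 1053 genes were higher and 2158 lower. Ifit3 rose 72-fold, and Ceacam1 fell by 1.72 ± 0.15 and Sgms1 by 1.71 ± 0.068. Over the 15 treated arrays 4812 genes had a slope over log10 dose, 1355 up and 3457 down. At least 1.5-fold, rises outnumbered falls in both (538 and 354 between the doses, 572 and 515 for the slope). Ifit3b (1.71 ± 0.14 log2 units per 10-fold of dose), Ifit3 (1.61 ± 0.15) and Ifit1 (1.56 ± 0.13) had the steepest rises, and Ceacam1 (-0.47 ± 0.04), Sgms1 (-0.46 ± 0.033) and Cpm (-0.41 ± 0.034) the steepest falls.

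**Figure D3:**
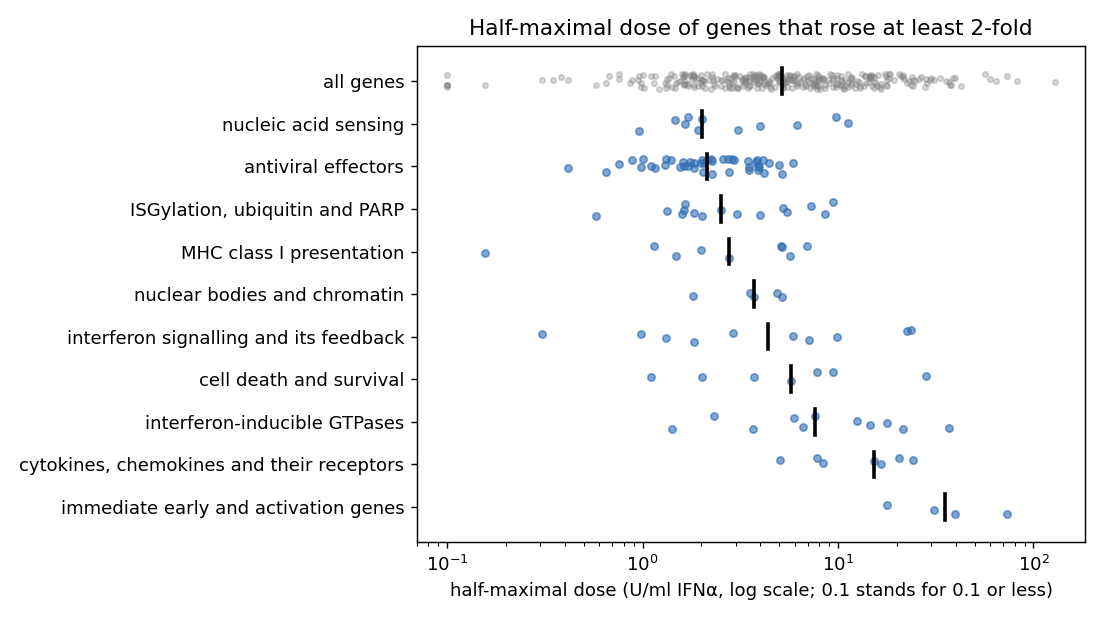
Half-maximal dose in U/ml (x axis, log scale; 0.1 stands for 0.1 or less) of genes that rose at least 2-fold at 1000 U/ml, for all 324 genes and for lists with at least 4 such genes; points are genes and bars medians. Medians ran from 2.02 U/ml for nucleic acid sensing to 35.4 U/ml for immediate early and activation genes on the log2 scale drawn here, and were 5.94 and 65 U/ml on linear values.

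Half-maximal doses of the 324 genes that rose at least 2-fold had a median of 5.15 U/ml (quartiles 2.57 and 10.8), and 214 lay between 1 and 10 U/ml. On linear values in place of log2 the median was 12.6 U/ml. On log2 values without 0 U/ml replicate 1 it was 3.16 U/ml, over genes chosen anew in that fit rather than the same 324. At 1 U/ml 262 genes were below 0.5 of their 1000 U/ml response and 2 were past it; at 10 U/ml 139 were past and 20 below; at 100 U/ml 305 were past. Usp18 reached 0.5 of its response at 1.83 U/ml (1.67 to 1.99 on leaving out an array), Mx1 at 2.14 (1.86 to 2.27), Ifit1 at 2.27 (2.11 to 2.38) and Cxcl10 at 5.04 (4.25 to 5.72). On linear values these genes reached it at 8.52, 15.2, 7.76 and 33.1 U/ml, so the ranges hold for the log2 scale only. The highest by this reading were Wfdc17 at 129 U/ml (34.1 to 345), Armcx6 at 82.1 (56.9 to 117), Jun at 73.4 (60.8 to 112), Tmem106a at 64.4 (45.8 to 90.7) and Prkcq at 60.2 (48 to 73.5), or at 181, 143, 164, 120 and 133 U/ml on linear values, where Cdh17 (129 U/ml) was above Tmem106a. Their order did not hold: Ccl3 was highest with a Hill curve (174 U/ml) and with 0.1 U/ml as the baseline (183), where Wfdc17 was at 73.5 and Tmem106a at 41.3, against 20.6 for Ccl3 by the main reading (0.1 to 103 on leaving out an array). The 5 lowest by the rule, Eif5a, Atp5d, Psmb4, Macrod2 and Rab22a at 0.1 U/ml or less, differed between the untreated arrays by SDs of 0.44 to 2.1, and Eif5a ranged from 0.1 to 349 U/ml on leaving out an array. Chosen after their values were seen, Irf9 (0.305 U/ml, 0.19 to 0.488) and Trim30a (0.65, 0.586 to 0.723), at 0.53 and 1.86 U/ml on linear values, were the 2 genes past 0.5 of the response at 1 U/ml by the test. List medians were 2.14 U/ml for antiviral effectors (45 genes), 2.76 for MHC class I (9 genes), 7.59 for GTPases (11 genes) and 15.2 for cytokines, chemokines and their receptors (7 genes), or 6.47, 6.33, 22.1 and 41.2 U/ml on linear values, a scale chosen for lists after the data were seen; differences between lists were not tested.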

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

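The tests of why falls outnumbered rises were chosen after that result was seen, as was leaving out predicted names among neighbouring genes.

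A signal appeared among probe sets outside the gene comparisons: 142 probe sets with several gene symbols or none rose at least 2-fold at 1000 against 0 U/ml, 85 of them among 1399 with several symbols and 57 among 2098 with none. The largest log2 changes were 3.91 and 4.36, and 3 and 5 fell at least 2-fold. The probe sets are not separate signals: the 85 form 32 groups that share a symbol, the largest of 15. Those 15 had log2 changes of 1.58 to 1.76, with limma adjusted p of 0.017 to 0.031. For the rises of 3.91 and 4.36 it was 5.2e-10 and 9.8e-10, so the count pools strong and borderline calls. In a comparison chosen after the count was seen, 56 of the 142 still rose at least 2-fold without 0 U/ml replicate 2 and 61 without 0 U/ml replicate 1.

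Falls outnumbered rises at 1000 against 0 U/ml, and the called falls had a median of -0.384 on the log2 scale beside -0.045 over all genes; since genes enter by being called, that size decides nothing, and the bound first set on it was wrong. The share of falls was 44.3% after median centring and 67.5% after quantile normalization; centring moves every gene of an array alike and so sets the share, which decides nothing, and normalization stays open. Without 0 U/ml replicate 2 the share stayed at 57.6%, which argues against that array as the source. With only the 1000 and 0 U/ml groups in the fit the share was 50.3%. At 1000 against 0.1 U/ml, falls were 67.2%, 64.2% after median centring and 66.2% after quantile normalization. In that comparison these scalings did not change which direction held more genes, though among changes of at least 1.5-fold falls were 39.7%. A biological effect of dose stays open.

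Genes differed in half-maximal dose: across the 324 genes, which are not independent replicates, half-maximal dose fell with the 1000 U/ml mean (Spearman rho -0.51, 95% bootstrap interval -0.6 to -0.42), as an intensity ceiling that flattens bright genes would give. Among the 162 dimmer genes rho was -0.37 (-0.5 to -0.22), which does not exclude a ceiling, and a rho of -0.17 with the 0 U/ml mean (-0.27 to -0.062) leaves a signal floor open. The log2 scale, on which larger responses may reach 0.5 of their change earlier, also stays open: rho with the log2 change was -0.38 on log2 and -0.15 (-0.25 to -0.05) on linear values. Differences between genes in sensitivity to dose stay open beside these.

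Genes that rose at least 2-fold lay next to one another. Of 19677 genes placed in order, 59 neighbouring pairs had both risen, against a median of 5 in 10000 random placements (permutation p = 1e-04, the smallest they can give). Pairs whose names differ in their first 3 letters numbered 25 (highest random count 13), which argues against tandem copies as the whole source, and 21 once overlapping gene models were left out (highest random count 13), which argues against overlap as the whole source. Among them are Rsad2 and Cmpk2, Parp14 and Dtx3l, and Psmb9 and Tap1, chosen after their values were seen. Shared regulation of neighbours may contribute, as a hypothesis; copies with unlike names and transcription running past a gene's end were not tested.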

How the results depend on the processing

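The array weights by the gene by gene method, 0.1 U/ml as the baseline of the half-maximal dose and the restriction to stable genes were chosen after seeing the data. Of 284 named results 214 were called, and 1 of these changed sign under any alternative: Atp5d, called at 1.43, was at -0.0475 to 2.91 on leaving out an array. Of the 214 calls, 178 held with only the groups compared (36 weaker), 179 at an adjusted p under 0.01, 181 at least 1.5-fold and 188 without 0 U/ml replicate 2 (25 weaker, 1 reversed); 194 to 212 held under each of the others that kept all 214, and 196 of 196 among genes above the median mean. The default array weights of limma did not converge (weight 22.9 for 100 U/ml replicate 1). Stricter thresholds lower counts by construction; otherwise the cause was not tested. Where 1 array was left at 0 U/ml, it is assumed to vary like the other groups. Signal over background limits dim genes, and was not given in the sources used here.

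Counts of called genes moved as follows. Default array weights gave 2060 at 1000, 396 at 10 and 85 at 1 against 0 U/ml, 2387 at 10 against 1, 5726 at 100 against 10, 3196 at 1000 against 100 and 4872 at 1000 against 0.1 U/ml. The gene by gene weights gave 1979, 1247, 394 and 84 at 1000, 100, 10 and 1 against 0 U/ml, and 2305, 2119 and 245 in the steps up to 10, 100 and 1000 U/ml. With only the groups compared the counts were 1865, 824, 320 and 57 against 0 U/ml, 1074 at 10 against 1 and 0 at 1000 against 100 U/ml (919 at an unadjusted p under 0.05 in the limma fit of all groups). A change of at least 1.5-fold left 965, 672, 301 and 110 against 0 U/ml, 184, 102 and 13 in the last 3 steps, 892 at 1000 against 0.1 U/ml and 1087 for the slope. An adjusted p under 0.01 left 1933, 1207, 387 and 90 against 0 U/ml and 239, 155 and 6 in the last 3 steps. Quantile normalization gave 1217 at 10 against 0 and 45 at 1000 against 100 U/ml; for the latter, median centring gave 10 and every probe set 12. On linear values the median half-maximal dose was 12.6 U/ml, with 53 genes past 0.5 of the response at 10 U/ml; with 0.1 U/ml as baseline it was 6.61, and over 299 stable genes 5.23. With an estimated correlation 10 of the 17 lists were called. By fry, which does not compare a list with other genes, ribosomal proteins (0.3), oxidative phosphorylation (0.47) and glycolysis (0.11) lost their call; among genes above the median mean these were at 0.079, 0.11 and 0.079 and heat shock genes at 0.076.

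On leaving out each array the counts ran from 1992 to 4631 at 1000, 1358 to 3933 at 100, 344 to 2645 at 10, 65 to 5250 at 1 and 0 to 2587 at 0.1 against 0 U/ml, lowest without 0 U/ml replicate 2 and highest without replicate 1. They ran from 75 to 112, 230 to 513, 112 to 532 and 4 to 33 in the steps up to 1, 10, 100 and 1000 U/ml, from 2455 to 3519 at 1000 against 0.1 U/ml and from 4160 to 5703 for the slope. The median half-maximal dose ran from 3.16 to 5.8 U/ml, genes below 0.5 of the response at 1 U/ml from 234 to 271, past 0.5 of the response at 10 U/ml from 119 to 198 and at 100 U/ml from 280 to 387, and called lists from 14 to 19.

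The other changes of sign were of uncalled log2 changes. At 1000 against 0 U/ml, quantile normalization gave Jak1 -0.129, Hdac1 -0.0592, Cdk4 -0.0594 and Hsp90aa1 -0.129; median centring gave Kynu 0.0243, Rel 0.0112 and Cycs 0.0353, and the mean of a gene's probe sets gave Cycs 0.116. In other contrasts quantile normalization gave Cd69 -0.0937 and Ifnar2 -0.0781 (1 against 0 U/ml), Ifnar2 -0.048 (0.1 against 0) and -0.0301 (1 against 0.1). At 0.1 against 0 U/ml Ifit1 was 0.0513 with default weights, 0.0436 with gene by gene weights and 0.00449 after median centring; at 1 against 0.1 U/ml Actb was 0.0159, 0.0164 and 0.0239. On leaving out an array, ranges at 1000 against 0 U/ml were -0.103 to 0.135 for Jak1, -0.00713 to 0.0402 for B2m, -0.0681 to 0.141 for Cd74, -0.133 to 0.263 for Hdac1, -0.152 to 0.0868 for Kynu, -0.264 to 0.048 for Cd79b, -0.135 to 0.336 for Cdk4, -0.0172 to 0.104 for Hsp90aa1, -0.176 to 0.133 for Cycs, -0.0436 to 0.405 for Ldha, -0.0207 to 0.44 for Cd2, -0.0899 to 0.861 for Ngp and -0.00548 to 0.176 for Actb. Actb ran from -0.071 to 0.11, -0.0852 to 0.0961, -0.0296 to 0.152 and -0.0264 to 0.155 at 100, 10, 1 and 0.1 against 0 U/ml, from -0.0248 to 0.0257 at 1 against 0.1 and from -0.0164 to 0.0483 at 100 against 10 U/ml. Ifnar2 ran from -0.0132 to 0.134 (1 against 0), -0.043 to 0.104 (0.1 against 0) and -0.00421 to 0.0592 (1 against 0.1), and at 0.1 against 0 U/ml Ifit1 from -0.213 to 0.141 and Ifnar1 from -0.0396 to 0.224. Adjusted p of lists that changed direction ran from 0.1 to 0.95 (cholesterol synthesis), 1.4e-05 to 0.65 (B cell identity), 0.0041 to 0.39 (MHC class II), 0.11 to 0.99 (type I interferon genes), 0.032 to 0.67 (germinal centre) and 0.65 to 0.98 (T cell markers).

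No general pairing of samples by replicate number was seen. Correlations of deviations over 40 same-numbered pairs ran from -0.554 to 0.608 with a median of -0.0675. Of these 10 were over 0.1, and 5 of 17 samples correlated best with their own number. Pairing at some doses stays open. On the second principal component replicates 1, 2 and 3 lay at 3.16, 14.7 and -12.3 at 100 U/ml. At 1000 U/ml they lay at 3.23, 7.53 and -9.25. With the replicate number as a block 2823 genes were called at 1000 against 0 U/ml and no total of called genes in a contrast moved by more than 1.5 times, though falls at 1 against 0 U/ml went from 107 to 51; of the 214 named calls 208 held, the median half-maximal dose was 5.33 U/ml, oxidative phosphorylation had an adjusted p of 0.084, and uncalled Cycs (0.0128) and Actb at 10 against 0 U/ml (-0.00528) changed sign.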

Other observations

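The tests of other splits of the samples were planned, and none here was chosen after its result was seen. Several fixed lists have not been described above. Of 20 genes of integrated and unfolded protein stress, 5 rose and 4 fell at 1000 against 0 U/ml, the same over the list alone (camera adjusted p = 0.18, and 0.62 with an estimated correlation): the chaperone Hspa5 rose 2.11-fold, Psat1 1.69-fold and Asns 1.55-fold, and Herpud1 fell by 0.91 ± 0.087. That list was called without 0 U/ml replicate 1 (0.037). Of 15 genes of the germinal centre, plasma cells and class switch, 2 rose (Bcl6 1.44-fold, Fas 1.4-fold) and 2 fell, among them Prdm1, which fell by 0.48 ± 0.12, the same over the list alone (camera adjusted p = 0.48; 0.032 without 0 U/ml replicate 1 and 0.29, direction down, without 0 U/ml replicate 2). Of 12 glycolysis genes 2 rose, Hk2 1.75-fold and Hk1 1.45-fold, and 1 fell (4 and 2 over the list alone; camera adjusted p = 0.012, but adjusted p = 0.54 with an estimated correlation). Of 33 genes of oxidative phosphorylation 1 rose and 3 fell (0 and 3 over the list alone; camera adjusted p = 0.043, direction up, but adjusted p = 0.62 with an estimated correlation); Uqcrb fell by 0.94 ± 0.11. Of 17 cholesterol synthesis genes 1 fell (0 over the list alone; camera adjusted p = 0.66). Of 27 ribosomal protein genes 1 rose (0 over the list alone; camera adjusted p = 0.01, but adjusted p = 0.57 with an estimated correlation), and of 11 heat shock genes 2 rose, the same over the list alone (camera adjusted p = 0.025, but adjusted p = 0.22 with an estimated correlation). Without 0 U/ml replicate 2 the adjusted p was 0.48 for glycolysis, 0.29 for oxidative phosphorylation and 0.13 for ribosomal proteins, and without 1000 U/ml replicate 3 it was 0.079, 0.3 and 0.076. For heat shock genes it was 0.059 without 0 U/ml replicate 1 and 0.079 without 1000 U/ml replicate 3.

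Each step between treated doses compares 3 arrays with 3, which make 10 splits, too few for a share under 0.05. The real split called 103, 382, 387 and 24 genes in the steps up to 1, 10, 100 and 1000 U/ml and 3211 at 1000 against 0.1 U/ml; in each of these 1 split, the real one, gave as many, and the highest of the other splits called 0. For the slope over log10 dose, 1 of 100 assignments of dose to the 15 arrays, the real one, called as many as 4812 genes. That is the smallest share 100 assignments can give, so chance is less likely but not excluded. The share also takes the arrays as independent, which the labels do not state. The highest of the others called 4001, so a wrong order of doses can also call many genes. How closely that order resembled the real one was not examined.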
